A study of Homo sapiens with 10 samples.

How the data were processed

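The series measured poly(A) RNA of H9 human embryonic stem cells by Illumina HiSeq sequencing, in 5 groups of 2 libraries: undifferentiated cells (ESC) kept without feeders, and cells 6 h, 12 h, 24 h and 48 h after induction with WNT and Activin A, with serum and Activin A after the first 24 h. Per the submitters' processing notes, reads were aligned with Bowtie2 to hg38. The deposited values are TPM, transcript abundance scaled to one fixed total per library, for each RefSeq transcript record, and the deposited file gave 10 columns of values, of which 0 could not be matched to a library. The upstream versions are not given.

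The unit was checked against the values. TPM multiplied by the span of a record, introns included, gave whole numbers of reads after division by 1 factor per library, within a tolerance of 0.01 reads, so TPM had been scaled by the gene span and not by exon length. The factor gave the reads behind each value, which are recovered from TPM. Of 5369 pairs of nested genes on 1 strand the inner had more reads in 0, and of 2773 on opposite strands in 265, which shows counting by strand. A nested gene's reads are therefore also counted for the gene around it. How spliced reads were treated is not given.

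The 73540 records, of which 4988 had no gene name and 4915 of these were named from the reference annotation, covered 27862 gene symbols. The longest span stood for each symbol; 2433 genes lie inside another on the same strand, and 96 symbols are on more than 1 chromosome. Reads over genes were 4232179 and 5397121 for ESC replicates 1 and 2, 3974173 and 4719306 at 6 h, 4045683 and 5031160 at 12 h, 4853700 and 4871975 at 24 h, and 3616575 and 4723816 at 48 h. Genes with at least 1 TPM in at least 2 libraries were tested (13717). Records with spans of up to 200 bases held 14.1% (48 h replicate 1) to 25.7% (6 h replicate 2) of the TPM. Ribosomal RNA records were those named as 18S, 28S, 45S, 5.8S or 5S and those inside a 45S record on the same strand.

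The groups, comparisons, fit, lists, naming rule and first set of alternatives were fixed before the data were examined. The plan allowed for counts or TPM; TPM was found, so log2(TPM + 1) was fitted with limma 3.58.1 (R 4.3.3) with an intensity trend, 1 coefficient per group, 10 libraries together and no replicate term. Each time was compared with ESC, and each time with the one before it, by moderated tests with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05; the F test compared all groups. Residual degrees of freedom were 5. Prior degrees of freedom, the weight given to the spread shared by genes of like level, were 5.80. Persistence was the share of genes called at 6 h that were called in the same direction at 48 h, with an exact binomial 95% interval. Relations between changes over genes were set beside 100 simulations in which only the ESC libraries were shared. Tests between 2 library measures, of which 2 were computed, were two-sided permutation tests.

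The 24 gene lists, chosen from general knowledge, were primed pluripotency, primitive streak and mesendoderm, definitive endoderm, WNT, Activin/Nodal, BMP and FGF/ERK targets, immediate-early and YAP targets, mesoderm, neuroectoderm, trophoblast, yolk sac and hepatic endoderm, epithelial adhesion, mesenchymal transition, cholesterol synthesis, ATF4, HIF1 and p53 targets, DNA replication, mitosis, chromosome architecture, replication-dependent histones, ribosomal proteins and mitochondrial transcripts. Members that passed the filter are called measured. They were 14 of 18 for the streak, 12 of 18 for WNT, 9 of 13 for BMP and 14 of 17 for endoderm. For mesoderm they were 6 of 16, for neuroectoderm 4 of 16, for trophoblast 1 of 11 and for yolk sac 4 of 14. A member under 1 TPM in both ESC libraries could pass only through later times, which favours members that rise. Members were counted as called over all genes and as called when adjusted over the list alone. Lists of at least 2 tested genes were compared with all other genes by camera with a preset correlation of 0.01 in the 4 comparisons with ESC (88 tests, adjusted together), and again with an estimated correlation and by fry. The values of 2 members of these lists are not reported here.

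Genes were named by rule: the 10 with the largest change in each direction at 6 h and 48 h and the 5 largest elsewhere, among genes with adjusted p under 0.05, at least 2-fold change, a mean of at least 5 TPM in the higher group, both libraries of each group on one side and a gene symbol; up to 4 called members of each list; and POU5F1, NANOG, SOX2, TBXT (listed as T), MIXL1, EOMES, GSC, SOX17, FOXA2, GATA6, CER1, CXCR4, NODAL, LEFTY1, LEF1, AXIN2, MYC, ID1, PAX6 and CDX2. Further members of lists and genes said to be chosen after their values were seen fall outside it, as do examples given as levels for a list with few calls.

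The alternatives planned were no filter, a filter of 5 TPM, a pseudocount of 0.1, rescaling by trimmed means (TMM, 30% and 5% trimmed) or upper quartiles, limma without the trend, a replicate term, the compared groups alone, a 2-fold minimum and leaving out each library. Alternatives added after the data were seen were spans over 200 bases (alone, with TMM, or without nested genes), limma-voom on recovered reads, the mean over the distinct spans of a symbol, leaving out the 3 libraries with the highest 18S level, the 18S level as a covariate, and TMM with a replicate term. The pipeline was tested on simulated data with 50 changed genes at each of 4 sizes, drawn from genes with a mean of at least 5 TPM. There the 48 h comparison made 10 false calls. Tables and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Records without a symbol were left out because they could not be named, and no library was left out.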

Results

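Poly(A) RNA was sequenced from H9 cells, an established line of human embryonic stem cells (ESC), before and during induction toward definitive endoderm, the germ layer that forms gut, liver and pancreas. Each of the 5 groups, ESC and 6 h, 12 h, 24 h and 48 h of induction, had 2 libraries, and the series asks whether the transcription changes of early differentiation last. Values are in TPM, transcript abundance scaled to one fixed total per library, given as mean ± SD (n = 2), and changes are log2 with their standard error (SE) from limma fitted to all 10 libraries. Between 3616575 (48 h replicate 1) and 5397121 (ESC replicate 2) reads were recovered over genes. At this depth, of 50 simulated changes of each size between 48 h and ESC, 1 was found at 2-fold, 11 at 4-fold, 39 at 8-fold and 43 at 16-fold. The changed genes were drawn from those with a mean of at least 5 TPM, so these rates do not cover lower genes. The same run made 10 false calls. The labels do not say that replicates were separate cultures, so each p measures only the spread between these samples.

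The part of each library taken by structural RNA varied. The level of 18S ribosomal RNA, the RNA of the small ribosomal subunit, lay between 213 TPM in ESC replicate 1 and 7838 TPM in 6 h replicate 2, and was 5921 TPM in ESC replicate 2 and 3543 TPM in 24 h replicate 1, for the highest of its records. The 228 records of ribosomal RNA, which list the same copies several times, together held 0.876%, 34%, 25.7% and 15.8% of the TPM of these 4 libraries, and 1.13% to 6.14% in the others. The median TPM of the genes was compared with it. Across the 10 libraries the median TPM was lower where 18S was higher (log2 values, Pearson's r = -0.878, permutation p = 2.0e-05, adjusted 4.0e-05; Spearman's rho = -0.939, permutation p = 2.8e-04, adjusted 5.6e-04). Without ESC replicate 1 and 6 h replicate 2, the libraries farthest from the median on that axis, r was -0.926. The median change of all 13717 genes tested was -0.19 at 6 h, 0.16 at 12 h, 0.01 at 24 h and 0.22 at 48 h against ESC, and changes of gene lists are given relative to it.

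At 6 h, genes of the primitive streak, the region of the early embryo from which mesoderm and endoderm arise, rose as a list. EOMES, a T-box factor needed for endoderm (chromosome 3, 27715949 to 27722715, hg38, span with introns), went from 1.9 ± 1.9 TPM in ESC to 135 ± 75.2 TPM, a log2 change of 5.61 (SE 0.95). MIXL1, a homeobox gene of the streak (chromosome 1, 226223618 to 226227055), stood at 2.96 ± 1.85 TPM and 166 ± 154 TPM. SP5, a target of WNT signalling, stood at 12.8 ± 12.1 TPM and 130 ± 72.4 TPM, and FGF8, a growth factor of the streak, at 0.445 ± 0.238 TPM and 14.5 ± 11.2 TPM. Of the 14 members measured, these 4 rose when adjusted over the list alone (adjusted p = 0.0015 for EOMES and FGF8 and 0.0051 for MIXL1 and SP5) and 0 over all genes, where EOMES had adjusted p = 0.105. The count over the list alone was 2 without 6 h replicate 1 and 8 without either 48 h library. All 14 lay above ESC, and the list's median change was 1.76 above that of all genes (camera adjusted p = 1.6e-32, adjusted p = 0.32 with an estimated correlation).

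Targets of the signals added to the medium rose as lists at 6 h. For the 14 members of the Activin/Nodal list the median was 1.12 above that of all genes (adjusted p = 2.0e-15, adjusted p = 0.32 with an estimated correlation). Adjusted over the list alone, 2 of them rose, EOMES and MIXL1, which are also on the streak list, and 0 over all genes. The count was 1 without ESC replicate 1 or 6 h replicate 1, 4 without either 12 h library, 7 without 6 h replicate 2 or 48 h replicate 1 and 6 without 48 h replicate 2. LEFTY1, a secreted inhibitor of Nodal whose reads can be shared with LEFTY2, stood at 106 ± 63.2 TPM in ESC and 579 ± 378 TPM at 6 h (adjusted p = 1), and NODAL, the ligand itself, at 20.7 ± 8.49 TPM and 62.6 ± 37.3 TPM (adjusted p = 1). Among 12 WNT targets SP5 rose when adjusted over the list alone, 0 rose over all genes, and the median was 0.91 above that of all genes (adjusted p = 4.8e-12, adjusted p = 0.32 with an estimated correlation). Without ESC replicate 1 or 6 h replicate 1 the count was 0, and without 6 h replicate 2 it was 2. The median was 0.52 higher without ESC replicate 1. The 9 BMP targets, with 0 called in either way (1 over the list alone without 6 h replicate 2 or either 48 h library), were 0.52 higher (adjusted p = 8.9e-06, adjusted p = 0.36 with an estimated correlation, and 0.0714 without 6 h replicate 2). T, the streak factor brachyury, had 0.566 TPM in ESC and 4.24 ± 1.4 TPM at 6 h, and ID1, a BMP target, 166 TPM and 333 ± 94.8 TPM. Neither passed a test.

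The cholesterol synthesis list moved the other way. All 25 measured members, targets of the sterol sensor SREBP2, lay below ESC at 6 h, with a median 0.44 below that of all genes (adjusted p = 4.6e-08, adjusted p = 0.67 with an estimated correlation). HMGCS1, which makes the precursor HMG-CoA, had 127 ± 27.2 TPM in ESC and 59.9 ± 30.5 TPM at 6 h, and INSIG1, which holds back sterol synthesis, 33.4 ± 11.1 TPM and 15.5 ± 7.8 TPM. Adjusted over the list alone 0 members fell, and 0 over all genes. Neuroectoderm markers were 1.08 lower (4 measured, 0 called either way, adjusted p = 0.00395, adjusted p = 0.32 with an estimated correlation), a call lost without 6 h replicate 1 (0.63 lower, adjusted p = 0.969), with no filter (0.351) or with a filter of 5 TPM (0.123). Over the list alone 2 fell without ESC replicate 2, 1 without either 12 h library and 3 without either 48 h library.

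Over all genes, 11 were called at 6 h, 7 higher and 4 lower (253 at an unadjusted p under 0.05), and each was a small RNA with a span of 52 to 164 bases. MIR1976, MIR3677, MIR6768, RNY3, SNORA36A, SNORA101B and SNORD136 were higher, and SNORD8, SNORD18B, MIR638 and RNVU1-6 lower. SNORD136 and RNVU1-6 were named after their values were seen. RNY3, a Y RNA, was listed at 0 in ESC and at 9.31 ± 0.0692 TPM at 6 h, and SNORD8 at 6.73 ± 2.73 TPM and 0. No library held more than 2 reads on any of the 11, and 1 read on such a span was worth 2.91 to 21.9 TPM. Most of them lie inside another gene, whose reads can be counted for them. These are MIR1976 (in RPS6KA1), SNORD136 (in GNL3), MIR3677, MIR6768, SNORA36A, SNORA101B, SNORD8, SNORD18B and MIR638. Of the 11, 4 and 6 were called without ESC replicates 1 and 2 and 2 and 3 without 6 h replicates 1 and 2, and only MIR1976 and MIR6768 in every fit without 1 library. Under the filter, and so not tested, were SNORD8 and RNVU1-6 without either ESC library and MIR3677, RNY3 and SNORA101B without either 6 h library. Tested and not called were SNORD136 without any 1 of these 4, SNORD8 and RNVU1-6 without either 6 h library, MIR638 and SNORD18B without ESC replicate 1 or either 6 h library, SNORA36A without either ESC library or 6 h replicate 1 and SNORA101B without either ESC library. The count was 7 without ESC replicate 1, 4 and 6 without 6 h replicates 1 and 2, 21 without either 12 h library, 18 without either 24 h library and 36 without either 48 h library, and 94 with the compared groups alone. Among 12923 genes with spans over 200 bases, a setting added after the data were seen, 38 were called, 18 higher and 20 lower (399 unadjusted), and with rescaling by trimmed means (TMM) 1 was (636 unadjusted). By limma-voom on recovered reads it was 0 (603 unadjusted).

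At 12 h, genes of the streak and of the WNT list stood above ESC. From 6 h to 12 h 0 members of either list were called, over the list alone or over all genes. GSC, the organizer gene goosecoid (chromosome 14, 94768223 to 94770162), went from 0.135 ± 0.191 TPM to 81.1 ± 84.3 TPM, a change of 5.65 (SE 1.05), and EOMES reached 214 ± 161 TPM (6.15, SE 0.95). Adjusted over the list alone 9 of the 14 streak members rose (T, MIXL1, EOMES, GSC, WNT3, FGF8, FGF17, NODAL and SP5; adjusted p from 7.1e-04 for EOMES to 0.0329 for NODAL) and 0 over all genes, where EOMES had adjusted p = 0.0633. The count was 5 without 12 h replicate 1. The median was 2.09 above that of all genes (adjusted p = 2.5e-19, adjusted p = 0.32 with an estimated correlation), 0.89 without 12 h replicate 1 and 3.39 without 12 h replicate 2. Of the WNT list, 4 members rose when adjusted over the list alone, SP5, APCDD1, DKK1 and DKK4, and 0 over all genes. DKK4, a secreted WNT inhibitor, had 0.0848 TPM in ESC and 116 ± 160 TPM at 12 h. This count was 0 without ESC replicate 1 or 12 h replicate 1, 1 without ESC replicate 2 and 2 without either 6 h library. The WNT median was 0.52 above that of all genes (adjusted p = 1.1e-05, 0.0779 without ESC replicate 1, adjusted p = 0.36 with an estimated correlation). It was 0.20 without ESC replicate 1 or 12 h replicate 1 and 0.78 without ESC replicate 2.

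The Activin/Nodal list was 1.56 higher at 12 h (adjusted p = 2.0e-12, adjusted p = 0.32 with an estimated correlation), with 7 members raised when adjusted over the list alone and 0 over all genes, and 3 without ESC replicate 2 or 12 h replicate 2. LEFTY1 rose to 629 ± 234 TPM (adjusted p = 0.0297 over the list alone). Cholesterol synthesis genes, 20 of 25 below ESC, were 0.36 lower (adjusted p = 1.9e-04, adjusted p = 0.90 with an estimated correlation, 0 members called either way). Without 12 h replicate 1 their median was 0.08 higher (adjusted p = 0.328), and without 12 h replicate 2 it was 0.78 lower. Over all genes 10 were called, 5 higher and 5 lower (308 unadjusted), 8 of them with spans of up to 200 bases. The other 2 were MFAP4, a protein of elastic fibres (chromosome 17, 19383442 to 19387219), which rose from 1.98 ± 0.331 TPM to 20.1 ± 0.48 TPM (2.83, SE 0.36, adjusted p = 0.0132), and FOXB2. This forkhead factor fell from 5.08 ± 2.06 TPM to 0.291 TPM (adjusted p = 0.0473), with at most 9 reads in a library. MFAP4 was not called without any 1 of the ESC or 12 h libraries, and FOXB2 not without either 6 h library or 12 h replicate 1. The largest changes by the naming rule were otherwise small RNAs, MIR1976, MIR6777, MIR6768 and SNORD136 higher and MIR6886, SNORD18B and SNORD8 lower. Of the 10, 2 were called without ESC replicate 1, MIR1976 and MIR6768, as in every fit without 1 library. MFAP4, MIR6777, SNORD136, MIR6886 and SNORD18B were not called there, nor MIR6777 without ESC replicate 2, either 6 h library or 12 h replicate 1, and FOXB2, SNORD8 and RNVU1-6, the last of the 10, were under the filter without either ESC library. The count was 4 without ESC replicate 1, 32 without 12 h replicate 2, 17 and 19 without 24 h replicates 1 and 2 and 44 and 41 without 48 h replicates 1 and 2, and 299 with the compared groups alone. Over 200 bases it was 83, and 3 with TMM, and by voom it was 0 (751 unadjusted).

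Of the 4 times, 24 h had the highest median of the streak program. MIXL1 rose from 2.96 ± 1.85 TPM in ESC to 963 ± 384 TPM (7.95, SE 1.20, adjusted p = 0.0256), EOMES to 415 ± 134 TPM (7.30, SE 0.95, adjusted p = 0.0106) and GSC to 136 ± 67.2 TPM (adjusted p = 0.0282). FGF17, a growth factor of the FGF8 family (chromosome 8, 22042753 to 22048808), went from 0.164 ± 0.0121 TPM to 254 ± 155 TPM (7.63, SE 0.95, adjusted p = 0.01). FGF4, which is made by the inner cell mass and the streak (chromosome 11, 69771016 to 69775403), rose from 0.788 ± 0.102 TPM to 143 ± 0.982 TPM (6.33, SE 0.79, adjusted p = 0.01) and had 4.5 ± 0.129 TPM at 48 h. Of the 14 streak members 13 rose when adjusted over the list alone and 4, MIXL1, EOMES, GSC and FGF17, over all genes. The median was 3.62 above that of all genes (adjusted p = 8.2e-34, adjusted p = 0.32 with an estimated correlation). The calls of FGF17, EOMES and FGF4 were lost without ESC replicate 1, and those of MIXL1 and GSC without either ESC or 6 h library or 24 h replicate 1.

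At 24 h definitive endoderm markers stood above ESC, in unequal amounts in the 2 libraries. SOX17, the transcription factor that defines this layer (chromosome 8, 54457935 to 54460896), went from 0.495 ± 0.201 TPM to 61.7 ± 67.7 TPM, and FOXA2, a pioneer factor of endoderm (chromosome 20, 22581004 to 22585463), from 0.165 TPM to 26.2 ± 10.9 TPM. CER1, a secreted inhibitor of Nodal, BMP and WNT (chromosome 9, 14719734 to 14722717), went from 97.3 ± 11.8 TPM to 2870 ± 2184 TPM. Of 14 members 8 rose when adjusted over the list alone (adjusted p = 0.0142 for SOX17, 0.00851 for FOXA2) and 0 over all genes, where SOX17 had adjusted p = 0.372. Without ESC replicate 2 or 24 h replicate 1 the count was 3. GATA6, a zinc finger factor of endoderm, was among the 8, at 14.8 ± 11.8 TPM. The median was 2.13 above that of all genes (adjusted p = 1.0e-13, adjusted p = 0.34 with an estimated correlation). At 6 h it was 0.14 and at 12 h 0.42, without a call in either test (adjusted p = 0.146 and 0.0616), though without 6 h replicate 1 the 6 h list was called (adjusted p = 1.4e-04), and the 12 h list was called without ESC replicate 2, 12 h replicate 2 or any 1 of the 24 h and 48 h libraries (adjusted p from 8.6e-05 to 0.0302). It was also called with a replicate block (0.0140), a pseudocount of 0.1 (0.00523), the compared groups alone (2.1e-05) or spans over 200 bases (4.7e-05), and 3 members were called over the list alone without either 48 h library.

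DKK4 and DKK1, secreted inhibitors of WNT, had their highest means at 24 h. DKK4 rose from 0.0848 TPM to 469 ± 533 TPM (adjusted p = 0.00162 over the list alone, 0.103 over all genes) and DKK1 to 68.7 ± 72 TPM. APCDD1, a membrane inhibitor of WNT, rose from 0.335 TPM to 6.29 ± 0.105 TPM and passed over all genes (adjusted p = 0.0355), though not without any 1 of the ESC, 6 h or 24 h libraries. With SP5 and SP8, 5 of the 12 WNT members rose adjusted over the list alone (median 1.35 above all genes, adjusted p = 3.0e-13, adjusted p = 0.32 with an estimated correlation). AXIN2, a feedback inhibitor of the same pathway, had 3.87 ± 0.544 TPM in ESC and 12.4 ± 2.18 TPM and was not called. On the Activin/Nodal list 7 of 14 rose adjusted over the list alone, 3 of them over all genes (EOMES, GSC and MIXL1), with a median 1.68 higher (adjusted p = 7.3e-13, adjusted p = 0.32 with an estimated correlation). Without ESC replicate 1 the count was 4. NODAL reached 104 ± 3.05 TPM (adjusted p = 0.00858 over that list). Among 9 BMP targets ID2, MSX1 and MSX2 rose adjusted over the list alone, and MSX1, a homeobox gene, over all genes, from 0.172 TPM to 7.07 ± 3.47 TPM (adjusted p = 0.0496, lost without either ESC or 6 h library or 24 h replicate 1). The list was 0.75 higher (adjusted p = 1.1e-06, adjusted p = 0.34 with an estimated correlation), and 1.72 higher without 24 h replicate 1.

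Of the pluripotency genes, GDF3, a TGF-beta family ligand, rose at 24 h from 4.62 ± 0.128 TPM to 36.4 ± 8.94 TPM and UTF1, a chromatin protein of stem cells, fell from 13.2 ± 4.22 TPM to 2.43 ± 0.731 TPM, both adjusted over the list alone (adjusted p = 0.00292 and 0.0295), with 0 over all genes. GDF3 was joined by 1 more gene without ESC replicate 1 or either 48 h library, no gene fell without ESC replicate 1, either 6 h library or 24 h replicate 1, and 2 fell without either 12 h or 48 h library or 24 h replicate 2. The 24 measured members were 0.42 lower (adjusted p = 0.0218, adjusted p = 0.95 with an estimated correlation), a call lost without ESC replicate 1 (0.0739) or 24 h replicate 1 (0.156). It was also lost with TMM (0.0586), upper quartiles (0.0582) or no filter (0.0688). At 6 h the list had 0 members called either way and adjusted p = 0.0821, under 0.05 without any 1 of the 12 h, 24 h and 48 h libraries (0.0182 to 0.0420), with 1 member lower over the list alone without either 48 h library. At 12 h UTF1 was the member that fell (adjusted p = 0.00247 over the list alone, 0 over all genes; 1 rose without ESC replicate 1 or 12 h replicate 2) and the list was 0.15 lower than all genes, with a median change of 0.01 and a mean of -0.13 (adjusted p = 0.0191, adjusted p = 0.95 with an estimated correlation). This call was lost without ESC replicate 1 (0.03 lower, 0.166), 12 h replicate 1 (0.06 lower, 0.187) or a filter (0.293), and the list was 0.35 and 0.25 lower without ESC replicate 2 and 12 h replicate 2. POU5F1, which encodes OCT4 (chromosome 6, 31164337 to 31170693), had 393 ± 87.3 TPM in ESC and 465 ± 209 TPM at 24 h, and NANOG 20.2 TPM and 43.1 ± 18 TPM. SOX2, which lies inside the span of SOX2-OT (chromosome 3, 181711924 to 181714435), had 344 ± 131 TPM and 201 ± 22.2 TPM. None of these 3 was called at any time. Cholesterol synthesis was 0.88 lower with all 25 below ESC (adjusted p = 3.0e-13, adjusted p = 0.45 with an estimated correlation), and 0 members were called over the list alone or over all genes. Over 200 bases with TMM, 14 fell over the list alone. HMGCS1 stood at 46.2 ± 12.1 TPM.

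Over all genes 30 were called at 24 h, 25 higher and 5 lower (666 unadjusted), 9 of them with spans of up to 200 bases. FOXB2 fell to 0 TPM from 5.08 ± 2.06 TPM, and the other falls named by the rule, SNORD8 and MIR5006, were small RNAs. The FOXB2 call was lost without 24 h replicate 1 and the MIR5006 call without ESC replicate 1, and FOXB2 and SNORD8 were under the filter without either ESC library. PCDH10, a protocadherin of cell adhesion, rose from 1.07 TPM to 22 TPM (adjusted p = 0.0183) and MFAP4 to 55.8 ± 5.94 TPM (adjusted p = 5.9e-04). PCDH10, lost without any 1 of the ESC or 24 h libraries, was chosen here after its values were seen, as was MFAP4, which was called without each library. Of the 30, 6 and 11 were called without ESC replicates 1 and 2 and 11 and 17 without 24 h replicates 1 and 2. The count was 7 without ESC replicate 1, 15 without 24 h replicate 1, 61 and 59 without 12 h replicates 1 and 2, and 156 and 150 without 48 h replicates 1 and 2, and 472 with the compared groups alone. Over 200 bases it was 280 (211 higher), with TMM 11 (1967 unadjusted) and by voom on all records 80.

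At 48 h the endoderm program was high, and far higher in replicate 1 than in replicate 2. SOX17 had 746 TPM in replicate 1 and 16.4 TPM in replicate 2, CXCR4, the chemokine receptor used to sort endoderm (chromosome 2, 136114349 to 136118155), 381 and 14.8 TPM, and CER1 10522 and 479 TPM, against group means of 0.495 TPM, 1.95 TPM and 97.3 TPM in ESC. Of 14 endoderm members 13 rose when adjusted over the list alone (adjusted p = 0.00372 for SOX17, 0.00567 for CXCR4 and CER1) and 2 over all genes, GPR37 and CST1. GPR37, a receptor for prosaposin (chromosome 7, 124743885 to 124766108), rose from 1.4 ± 0.418 TPM to 19.4 ± 1.03 TPM (3.09, SE 0.37, adjusted p = 0.0061). CST1, a cystatin protease inhibitor (chromosome 20, 23747553 to 23750937), rose from 2.35 ± 1.8 TPM to 42.6 ± 0.792 TPM (3.81, SE 0.47, adjusted p = 0.00695). The call of GPR37 was lost without ESC replicate 1. CST1 was called without each library in turn, and its reads can be shared with its close relatives CST2 and CST4. FOXA2 (65.8 ± 86.7 TPM) and GATA6 (34 ± 46.4 TPM) were among the 13. Without 48 h replicate 1 the count over the list alone was 7. The median was 3.04 above that of all genes (adjusted p = 1.7e-13, adjusted p = 0.34 with an estimated correlation), 1.28 without 48 h replicate 1 and 4.71 without 48 h replicate 2.

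**Figure D1:**
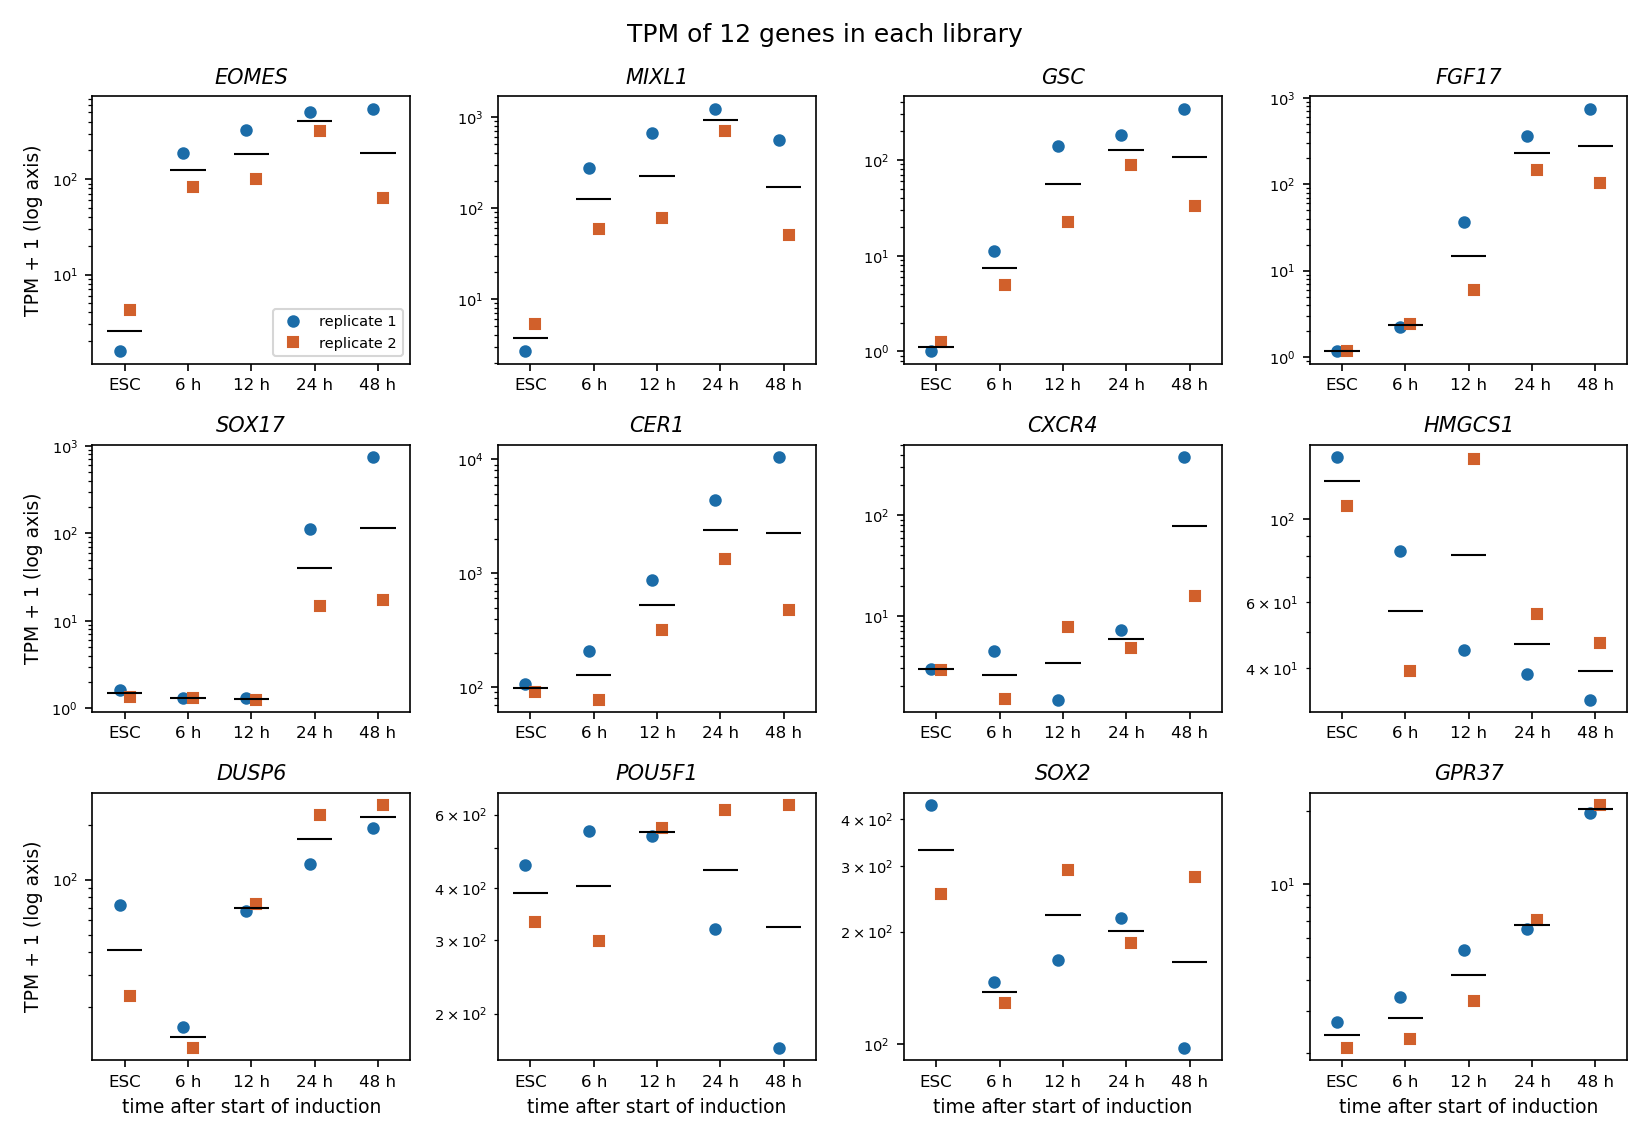
TPM + 1 on a log axis against time of induction (ESC, then 6 h, 12 h, 24 h and 48 h) for 12 genes, with circles for replicate 1, squares for replicate 2 and a line through the geometric means. At 48 h SOX17 stands at 746 TPM in replicate 1 and 16.4 TPM in replicate 2, while GPR37 stands at 18.6 and 20.1 TPM.

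By the SD of the gap over genes, the 48 h replicates differed more than those of any other group. It was 0.901 log2, against 0.664 to 0.732 in the other groups, and their correlation over genes was 0.883, against 0.922 to 0.934 (genes are not independent replicates). Genes over 2-fold apart in TPM were 1814 at 48 h and 3099 at 6 h, and after TMM 1680 at 48 h against at most 792 in the other groups. POU5F1 had 164 TPM in replicate 1 and 631 TPM in replicate 2, opposite in order to SOX17, whereas HMGCS1 (31.9 and 45.7 TPM), DUSP6 (190 and 254 TPM) and IER3 (2161 and 1460 TPM) stood on the same side of ESC in both. The 18S level was 278 TPM in replicate 1 and 378 TPM in replicate 2.

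Streak genes were still up at 48 h, 8 of 14 when adjusted over the list alone and 3 over all genes: FGF17 at 427 ± 460 TPM (7.90, SE 0.95, adjusted p = 0.0061), EOMES at 305 ± 343 TPM (adjusted p = 0.0257) and GSC at 188 ± 220 TPM (adjusted p = 0.0294). The median was 2.17 above that of all genes (adjusted p = 5.8e-09, adjusted p = 0.40 with an estimated correlation), and 1.14 without 48 h replicate 1. T was back at 0.509 TPM. The FGF17 call was lost without ESC replicate 1, the EOMES call without that or either 6 h library, and the GSC call without either ESC or 6 h library. Of the WNT list 7 of 12 rose adjusted over the list alone and 0 over all genes (2 without ESC replicate 1, 3 without 48 h replicate 1), with a median 1.33 higher (adjusted p = 9.1e-05, adjusted p = 0.42 with an estimated correlation), and 0.71 higher without 48 h replicate 1. MYC, a regulator of growth and one of the 7, went from 30 TPM to 87 ± 2.5 TPM (adjusted p = 0.0227 over the list alone). Of the Activin/Nodal list 9 of 14 rose adjusted over the list alone, 2 of them over all genes (EOMES and GSC), with 4 without ESC replicate 2 or 48 h replicate 1 (median 1.37 higher, adjusted p = 1.7e-08, adjusted p = 0.34 with an estimated correlation). LEFTY1 was among them at 1020 ± 1132 TPM. Of 9 BMP targets ID2 and SMAD6 rose adjusted over the list alone and 0 over all genes, and 0 either way without 48 h replicate 1 or either ESC library. The list was 0.78 higher (adjusted p = 0.0192, adjusted p = 0.76 with an estimated correlation), a call lost without ESC replicate 1 (0.0975), either 6 h library (0.0530 and 0.0503) or 48 h replicate 1 (0.11 higher, 0.605). It was also lost with no filter (0.0670), a filter of 5 TPM (0.158) or the compared groups alone (0.0960).

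Immediate-early genes and targets of the FGF/ERK cascade rose together at 48 h, after the change to medium with serum. IER3, an early response gene (chromosome 6, 30743199 to 30744550), rose from 208 ± 3.67 TPM to 1811 ± 496 TPM (3.09, SE 0.39, adjusted p = 0.00766, lost without ESC replicate 1). Of the 17 immediate-early and YAP targets, 11 rose adjusted over the list alone and 1, IER3, over all genes (5 over the list alone without ESC replicate 2), with a median 1.25 higher (adjusted p = 8.8e-11, adjusted p = 0.34 with an estimated correlation). FOS, a subunit of AP-1, went from 8.64 TPM to 43.5 ± 2.78 TPM and ANKRD1, a YAP target, from 6.23 TPM to 77.4 ± 61.1 TPM (adjusted p = 0.00808 and 0.00769 over the list alone). Of 15 FGF/ERK feedback targets 8 rose adjusted over the list alone and 0 over all genes (median 0.68 higher, adjusted p = 3.2e-05, adjusted p = 0.43 with an estimated correlation). DUSP6, the phosphatase that switches off ERK, went from 46.8 ± 34.8 TPM to 222 ± 45.5 TPM and DUSP4 from 2.44 TPM to 22.1 ± 13.8 TPM (adjusted p = 0.00921 and 0.00563 over the list alone). Without ESC replicate 1 that count was 5, without ESC replicate 2 it was 0 and without 48 h replicate 1 it was 2.

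At 24 h 2 FGF/ERK targets, DUSP6 and IL17RD, and 1 immediate-early gene, IER3, rose adjusted over their lists alone, with 0 over all genes. The medians were 0.32 and 0.71 higher (adjusted p = 0.00294 and 1.1e-05, adjusted p = 0.67 and 0.52 with an estimated correlation). The FGF/ERK median was 0.62 without ESC replicate 1, 0.57 without 24 h replicate 1 and 0.13 without 24 h replicate 2, and the immediate-early median 1.12 and 0.26 without 24 h replicates 1 and 2. The FGF/ERK count was 0 without ESC replicate 2 or either 24 h library, and the immediate-early count was 2 without either 48 h library. IER3 was also the 1 immediate-early gene that rose at 12 h adjusted over the list alone (adjusted p = 0.0149, 0 over all genes), and not without either ESC or 12 h library or 24 h replicate 2.

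Genes of hypoxia and glycolysis rose in part at 48 h. BNIP3, a HIF1 target at mitochondria, went from 5.7 ± 0.883 TPM to 42.8 ± 8.76 TPM (2.70, adjusted p = 0.0465, lost without either ESC library or 48 h replicate 1). SLC2A3, the glucose transporter GLUT3, rose from 121 ± 16.3 TPM to 715 ± 130 TPM (adjusted p = 0.00354 over the list alone), with reads that can be shared with SLC2A14. Of 21 members 9 rose adjusted over the list alone and 1, BNIP3, over all genes. Without ESC replicate 2 or 48 h replicate 2 the first count was 2. The median was 0.36 higher (adjusted p = 0.00143, 0.493 without 48 h replicate 2, adjusted p = 0.83 with an estimated correlation). It was 0.69 without ESC replicate 1, 0.60 without 6 h replicate 1 and 1.12 without 48 h replicate 1.

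At 48 h cholesterol synthesis was 1.10 below the median of all genes with 22 of 25 members below ESC (adjusted p = 1.0e-13, adjusted p = 0.45 with an estimated correlation). Over all genes 0 members were called. The 21 DNA replication genes were 0.52 lower (adjusted p = 3.2e-05, adjusted p = 0.83 with an estimated correlation, 0 called either way). MCM5, a subunit of the replicative helicase, had 39.9 ± 16.3 TPM and 20.8 ± 4.1 TPM. Of the pluripotency list, UTF1 fell to 1.31 ± 1.85 TPM over all genes (-2.87, adjusted p = 0.0491, lost without either ESC or 6 h library or 48 h replicate 1). ZIC2, a factor of neural and stem cells, and GDF3 rose adjusted over the list alone (0 rose without ESC replicate 2 and 1 without ESC replicate 1 or either 48 h library; 2 fell without either 12 h library and 4 without 48 h replicate 2). The list was 0.80 lower (adjusted p = 3.9e-05, adjusted p = 0.67 with an estimated correlation), 0.31 without 48 h replicate 1 and 1.26 without 48 h replicate 2. POU5F1 had 398 ± 330 TPM, NANOG 35.5 TPM and SOX2 188 ± 130 TPM, with no call.

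Over all genes 55 were called at 48 h, 45 higher and 10 lower (1406 unadjusted), 11 of them with spans of up to 200 bases. DIO3, the enzyme that inactivates thyroid hormone (chromosome 14, 101561351 to 101563452), was listed at 0 in ESC and at 36.2 ± 28.5 TPM (adjusted p = 0.00429). PCDH10 rose to 40.9 ± 4.84 TPM (4.37, adjusted p = 0.0061, lost without ESC replicate 1) and MFAP4 to 44.6 ± 6.44 TPM (adjusted p = 0.00377). CNMD, chondromodulin, fell from 7.92 ± 3.56 TPM to 0.326 TPM (-2.71, adjusted p = 0.0287, lost without ESC replicate 1 or 48 h replicate 1) and FOXB2 to 0 TPM (adjusted p = 0.00839). The other genes named by the rule were small RNAs: MIR6785, MIR6777 and SNORD124 higher, and SNORD8, SNORD6, SNORD18B, SNAR-E and SNORD116-13 lower. Without either ESC library the calls of MIR6785, MIR6777, SNORD124, SNORD6 and SNORD116-13 were lost, without either 6 h library those of MIR6777, SNORD124 and SNORD116-13, and without ESC replicate 1 that of SNORD18B. SNAR-E was lost without any 1 of the ESC or 6 h libraries, FOXB2 and SNORD8 were under the filter without either ESC library, and DIO3 and MFAP4 were called without each library. Of the 55, 6 and 14 were called without ESC replicates 1 and 2, 27 without either 6 h library and 34 without 48 h replicate 1. The count was 7 and 25 without ESC replicates 1 and 2, 30 without either 6 h library, 83 without 12 h replicate 1 and 437 without 48 h replicate 2, and 557 with the compared groups alone. Over 200 bases it was 551, 449 higher and 102 lower. With TMM it was 270, 156 higher and 114 lower, and 116 genes were called in both. By voom on all records it was 354.

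Between neighbouring times, most calls over all genes were small RNAs. From 12 h to 24 h the metallothioneins MT1X and MT2A, which bind zinc and copper, rose from 6.7 ± 2.92 TPM to 277 ± 72.9 TPM (5.20, SE 0.75, adjusted p = 0.0359) and from 19.4 ± 0.95 TPM to 398 ± 142 TPM (adjusted p = 0.043). Members of this family share sequence, so reads can be shared between them, and both calls were lost without either 6 h library, 12 h replicate 1 or either 24 h library, that of MT2A also without 12 h replicate 2. Adjusted over their lists alone, FGF17, MESP1, LHX1 and APLNR of the streak, SOX17 and CST1 of endoderm and MSX1, MSX2 and ID3 of the BMP targets rose over this step, with 0 of them over all genes. SOX17 rose by 4.99 (SE 1.36) and APLNR, the apelin receptor, by 3.12 (SE 0.50). From 24 h to 48 h T, MESP1 and APLNR fell adjusted over the streak list alone, by 3.25, 1.53 and 2.24, as did MSX1 over the BMP list, while GPR37, ANKRD1, BNIP3, SLC2A3 and APOA2, an apolipoprotein, rose adjusted over their lists alone, with 0 of these over all genes. From 6 h to 12 h DUSP6 rose adjusted over its list alone, from 12.8 ± 2.57 TPM to 69.3 ± 4.1 TPM, as did HESX1, a homeobox gene of the anterior embryo. Over the list alone, HIST2H4A and HIST2H4B, a pair of histone genes with 1 record between them, rose and HIST1H2BJ fell from 12 h to 24 h, when SIX3 also rose.

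Over all genes 5 were called from 6 h to 12 h (0 higher, 5 lower; 196 unadjusted), 13 from 12 h to 24 h (10 higher, 3 lower; 336 unadjusted) and 12 from 24 h to 48 h (4 higher, 8 lower; 623 unadjusted). The small RNAs named by the rule were SNORA101B, SNORA36A, RNY3, MIR3677 and MIR6886 for the first step, MIR6886, SNORD18B, MIR6861, SNORD136, MIR5006 and MIR1976 for the second, and SNORD99, MIR5006, SNORA36A, SNORD142, MIR6768, MIR6861, SNORD18B, SNAR-E and SNORD6 for the last. In the first step 0 and 1 of the 5 were called without 6 h replicates 1 and 2, where SNORA101B, RNY3 and MIR3677 were under the filter, and MIR6886 and SNORA36A were also lost without 12 h replicate 1 and SNORA36A without 12 h replicate 2. In the second, 7 of the 13 were called without either 6 h library or 12 h replicate 1, and 4 and 3 without 24 h replicates 1 and 2. MIR5006 was lost in all 5 of these fits and MIR6886 in all but that without 24 h replicate 1, and MIR6861 was under the filter without either 24 h library. In the last, 6 of the 12 were called without either 24 h library, where MIR5006 and SNORD99 were lost and MIR6861 was under the filter, as SNORD142 was without either 48 h library, and MIR5006 was also lost without either 6 h library. The first count was 2 without 6 h replicate 1, 10 without either ESC library, 14 without 12 h replicate 2, 11 without either 24 h library and 22 without either 48 h library. The second was 25 without 12 h replicate 2, 7 without 24 h replicate 2 and 70 and 62 without 48 h replicates 1 and 2. The last was 28 and 26 without 12 h replicates 1 and 2 and 61 and 92 without 48 h replicates 1 and 2. With the compared groups alone the counts were 107, 50 and 40, over 200 bases 20, 95 and 124, with TMM 0, 2 and 0 (278, 999 and 1656 unadjusted), and by voom on all records 0 each (239, 1060 and 1754 unadjusted).

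**Figure D2:**
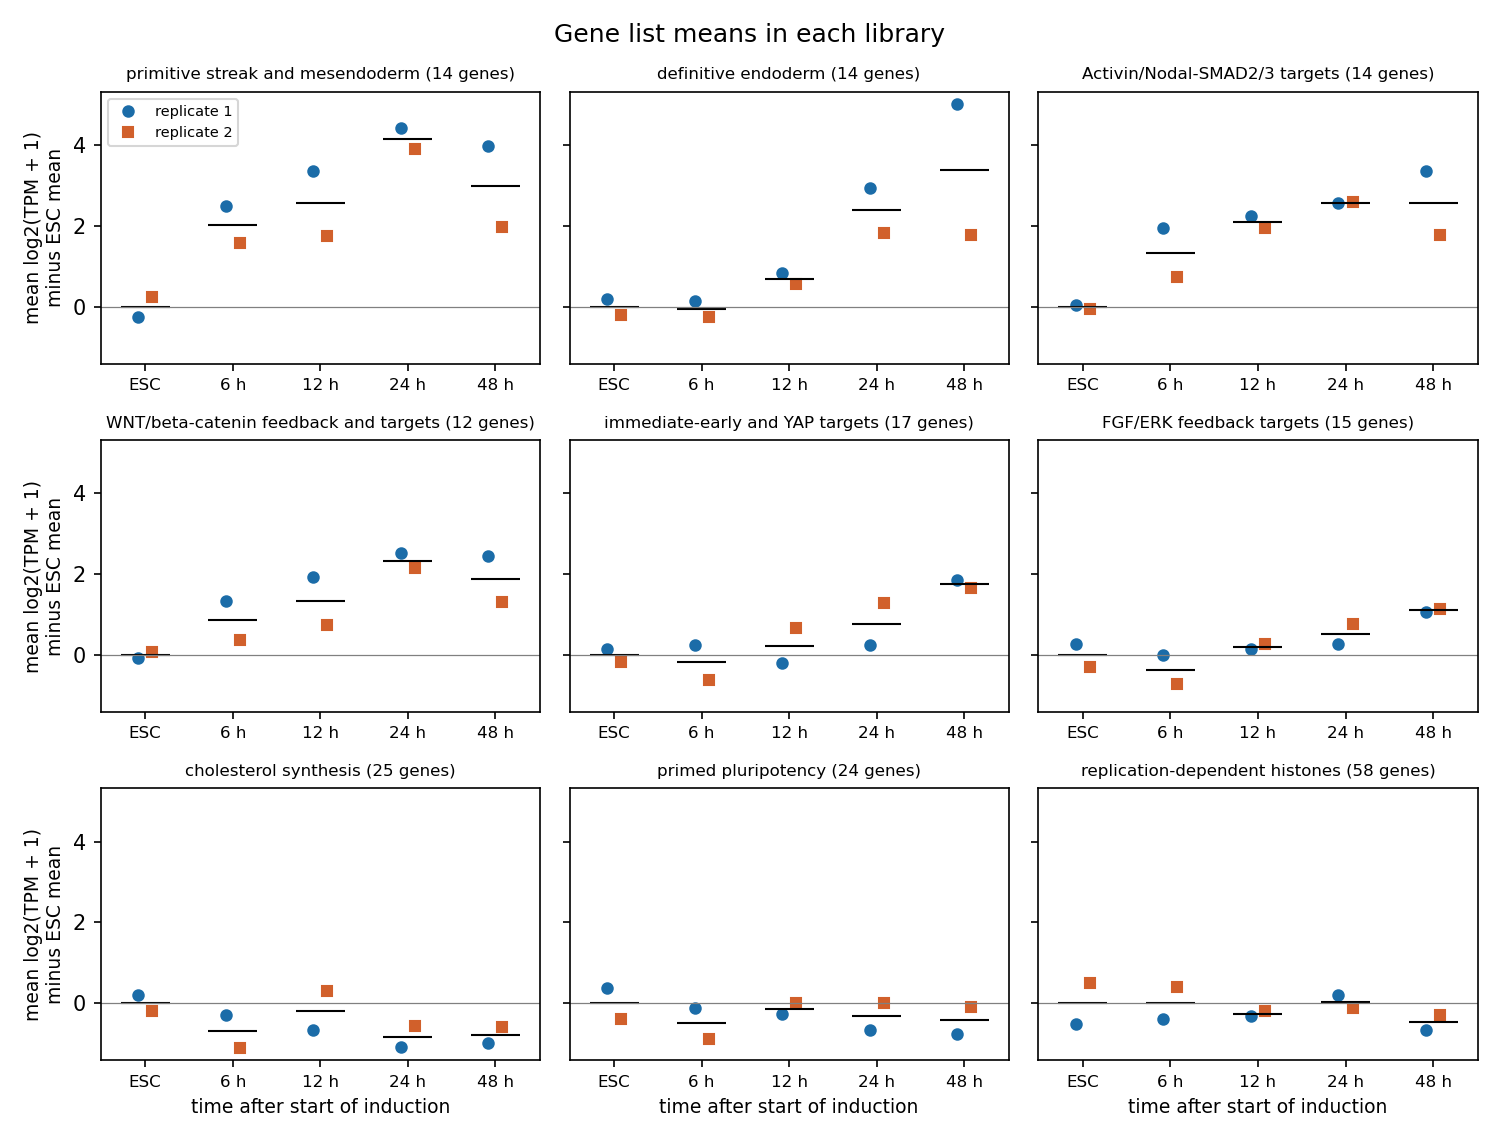
Mean log2(TPM + 1) of the members of 9 gene lists minus the mean of the ESC libraries, against time of induction, with a point per library and lines through the group means. The streak list is highest at 24 h, the endoderm points lie farthest apart at 48 h, and the group means of the cholesterol synthesis list lie below ESC, with 12 h replicate 2 above both ESC libraries.

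Across the whole course, 66 genes differed among the 5 groups by limma's F test. Their highest mean fell at 48 h for 29, at 24 h for 20, at 12 h and in ESC for 7 each and at 6 h for 3. The lowest was in ESC for 34 and at 6 h for 24, with ties given to the earliest group. Several small RNAs were tied at 0 TPM, such as MIR6861, which was at 0 in every group but 24 h and is counted under ESC. SLC30A1, a zinc exporter, was among them (adjusted p = 0.0431, chosen after its values were seen), at 9.86 ± 2.2 TPM in ESC and 104 ± 22.8 TPM at 24 h. The count was 28 and 34 without 6 h replicates 1 and 2, 120 and 130 without 12 h replicates 1 and 2, and 230 and 408 without 48 h replicates 1 and 2. Over 200 bases it was 716, and 9 with TMM.

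The question whether early changes last was put to the 11 genes called at 6 h. At 48 h 4 of them (36.4%, exact 95% interval 10.9% to 69.2%) were called in the same direction, SNORD8, SNORD18B and RNVU1-6 lower and SNORA36A higher, 0 in the opposite one, and 7 were not called. Lists drawn independently would share 0.00292 lower and 0.0230 higher genes, but both comparisons use the same ESC libraries, which alone makes calls shared, and all 11 rest on 2 reads or fewer in a library. The share ranged from 0% to 47.2% when 1 library was left out, with 0% without 6 h replicate 1. EOMES, the streak gene nearest to a call at 6 h, was 5.61 above ESC at 6 h and 6.18 above it at 48 h, whereas T was 3.22 above at 24 h and -0.04 at 48 h.

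The first step, 6 h minus ESC, and the last step, 48 h minus 24 h, share no library and had a correlation of -0.115 over 13717 genes (rho = -0.115; r = -0.114 with TMM; genes are not independent replicates). The share with the same sign moves with the median of all genes and was 30.4%, and 44.4% with TMM. Leaving out 1 library gave correlations of -0.17 to 0.0054, the highest without ESC replicate 1. The 6 h and 48 h changes against the same ESC libraries had r = 0.350 (rho = 0.302) and a covariance of 0.114, and 0.343 and 0.112 with TMM. With the shared ESC libraries alone and no true change, 100 simulations gave r = 0.498 and a covariance of 0.127, and 0.496 and 0.1003 with TMM. The share with the same sign, 41.9% as deposited, was 59.5% with TMM, against 66.8% simulated. The simulated r and share follow from the sharing of libraries alone, whatever the genes, so neither is a test. The observed covariance lay under the simulated one as deposited and above it with TMM. The simulation drew on each gene's moderated spread over all 10 libraries, and not on the spread of the ESC libraries themselves. The order of the observed and simulated covariances therefore cannot tell whether the shared libraries account for the whole relation.

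Markers of other cell types stayed low or mixed, and most members of these lists did not pass the filter. Of 6 mesoderm genes MESP1, NKX2-5 and SNAI2 rose at 24 h adjusted over the list alone and 0 over all genes, to 1.9 TPM, 1.8 TPM and 2.07 TPM (1 without either ESC library and 0 without 24 h replicate 2). The list was 0.84 higher at 24 h (adjusted p = 0.0109, adjusted p = 0.40 with an estimated correlation), a call lost without ESC replicate 1 (0.294), 24 h replicate 2 (0.10 lower, 0.864) or 48 h replicate 1 (0.104). It was also lost with TMM (0.0907), upper quartiles (0.0924), a pseudocount of 0.1 (0.0848), a filter of 5 TPM (0.756) or the compared groups alone (0.0960). Of 4 neuroectoderm genes SIX3, a homeobox factor of the forebrain, was listed at 0 in ESC and rose to 4.3 ± 3.51 TPM at 24 h and 3.79 ± 1.95 TPM at 48 h, adjusted over the list alone (adjusted p = 0.00173 and 0.00191), with 0 over all genes. Without ESC replicate 1 the 24 h count was 2. Over the list alone, 1 and 2 members fell at 24 h without either 12 h and either 48 h library, and 2 at 48 h without 48 h replicate 2. TFAP2C was the 1 trophoblast gene of 11 that passed the filter. It was lower than in ESC at every time (from 14.7 ± 2.86 TPM to 2.32 ± 1.83 TPM, unadjusted p = 0.00123 at 48 h) and was not called over all genes (adjusted p = 0.124). Of 4 yolk sac and hepatic genes AFP, alpha-fetoprotein, fell at 24 h and 48 h and APOA2 rose to 7.45 ± 8.75 TPM at 48 h, adjusted over the list alone, with 0 over all genes. AFP fell neither time without any 1 of the ESC or 6 h libraries, at 24 h not without 24 h replicate 1, at 48 h not without 48 h replicate 1, and APOA2 did not rise without either 48 h library. The list test gave adjusted p = 0.80 or more. PAX6, of neuroectoderm, CDX2, of trophoblast and hindgut, and LEF1, of WNT signalling, did not reach 1 TPM in 2 libraries and were not tested.

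Of 13 epithelial genes 0 were called either way at any time, and the list was 0.32 lower at 24 h (adjusted p = 0.0304, adjusted p = 0.90 with an estimated correlation), a call lost without ESC replicate 2 (0.0700), 12 h replicate 1 (0.0510), 24 h replicate 1 (0.17 lower, 0.251) or either 48 h library (0.0559 and 0.0519). It was also lost with no filter (0.0861) or the compared groups alone (0.152). CDH1, E-cadherin, had 9.53 ± 0.947 TPM in ESC and 7.77 ± 2.28 TPM at 48 h. Of 11 mesenchymal genes SNAI1, which represses CDH1, rose at 24 h, and CDH2, N-cadherin, SNAI1, MMP2, MMP14 and COL5A1 rose and COL1A1, a collagen chain, fell at 48 h, adjusted over the list alone, with 0 over all genes. SNAI1 went from 3.41 ± 1.06 TPM to 21.4 ± 0.78 TPM and COL1A1 from 80.8 ± 27.9 TPM to 22.6 ± 10.4 TPM. The 24 h count was 0 without ESC replicate 2 or 24 h replicate 2, 2 without 24 h replicate 1 and 3 without either 48 h library, and 1 fell without either 6 h or 48 h library. The 48 h counts were 0 without either ESC library, and 2 higher and 0 lower without 48 h replicate 1. At 48 h the list was 0.92 higher (adjusted p = 0.0191, adjusted p = 0.53 with an estimated correlation), a call lost without ESC replicate 1 (0.51 higher, 0.334), either 6 h library (0.0531 and 0.0503) or 48 h replicate 2 (0.0519). It was also lost with TMM (0.0620) or upper quartiles (0.0634), and the list was 0.45 higher without 48 h replicate 1.

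The remaining lists covered stress, the cell cycle and RNA quality. Of 20 ATF4 targets VLDLR, a lipoprotein receptor, rose at 48 h adjusted over the list alone (adjusted p = 0.034, 0 over all genes). It did not without either ESC or 6 h library or 48 h replicate 2, and 2 genes did without 48 h replicate 1. The ATF4 list was 0.33 lower at 6 h (adjusted p = 0.0349, adjusted p = 0.97 with an estimated correlation). This call was lost without ESC replicate 2 (0.07 lower, 0.702) or 6 h replicate 1 (0.04 lower, 0.461), and with TMM (0.291), upper quartiles (0.251), no filter (0.0510) or a filter of 5 TPM (0.179). Of 17 p53 targets 0 were called either way (over the list alone 1 rose at 48 h without either 12 h library or 48 h replicate 2, and 1 fell without the last), and the list was 0.21 lower at 6 h (adjusted p = 0.0119, adjusted p = 0.83 with an estimated correlation). This call was lost without ESC replicate 2 (0.0077 lower, 0.702) or 6 h replicate 1 (0.14 lower, 0.501), and with TMM (0.0668), upper quartiles (0.0651) or the compared groups alone (0.0513). The list was 0.44 and 0.35 lower without ESC replicate 1 and 6 h replicate 2. The 20 mitosis genes and the 20 genes of chromosome architecture (cohesin, CTCF and lamina) had 0 calls either way (1 architecture gene rose at 48 h over the list alone without either 6 h library) and no list call at any time, although mitosis was 0.23 lower at 48 h with TMM or upper quartiles (adjusted p = 0.0155 and 0.0164). Of 80 ribosomal protein genes 0 were called either way, and the list was 0.16 higher at 12 h (adjusted p = 0.0191, adjusted p = 0.97 with an estimated correlation), a call lost without ESC replicate 2 (0.652), 12 h replicate 1 (0.671), either 48 h library (0.0820 and 0.0756) or with the compared groups alone (0.382). Its median was 0.03 and 0.02 lower without ESC replicate 2 and 12 h replicate 1, and 0.35 and 0.33 higher without ESC replicate 1 and 12 h replicate 2. With TMM the ribosomal list was also called at 6 h (0.13 higher, adjusted p = 1.3e-04) and 24 h (0.16 higher, 7.1e-04), as with upper quartiles (1.2e-04 and 0.00101). The 58 replication-dependent histone genes, whose transcripts lack poly(A), were 0.15 higher at 6 h (adjusted p = 0.0112), although their median change was -0.04 before the shift of all genes was removed, and 0.42 lower at 12 h and 0.77 lower at 48 h (adjusted p = 2.0e-08 and 1.5e-09). Adjusted p = 0.83 at 6 h and 0.34 at 12 h and 48 h with an estimated correlation. HIST1H2BJ, of this list, fell at 24 h adjusted over the list alone, not without ESC replicate 1 or 24 h replicate 2, with 0 over all genes. These histone values turned sign without ESC replicate 1 or 6 h replicate 2 at 6 h (-0.59 and -0.52) and without ESC replicate 2 at 12 h (0.10) and 48 h (0.03). They were 0.95 and 1.04 without ESC replicate 2 and 6 h replicate 1 at 6 h, and -1.34 and -1.35 without ESC replicate 1 at 12 h and 48 h. The 6 h call was lost with TMM (0.591), upper quartiles (0.684) or no filter (0.124), and the 48 h call without ESC replicate 2 (0.962). The mitochondrial list had 0 records in the deposited values.

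By camera with a preset correlation 40 of the 88 list tests were called, and 0 with an estimated correlation, where the lowest adjusted p was 0.32. By fry, which tests whether the members of a list move one way on balance, 0 were called (lowest adjusted p = 0.27). By its mixed form, for change in either direction, the streak and mesoderm lists at 24 h and the endoderm, mesenchymal, FGF/ERK and immediate-early lists at 48 h were called (adjusted p = 0.043 for each).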

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

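The over-200-base, voom, 18S, span-mean and TMM-with-replicate-term alternatives were chosen after the data were seen. The others were planned. Of 264 named gene values 0 changed direction in a called fit. This was partly fixed beforehand, since the rule took the largest changes only where both libraries of each group lay on one side. Leaving out 1 library could not turn those. Of the 70 called values 15 were called in every fit without 1 library. In 1 or more of these fits 43 were not called and 16 were under the filter. Under every setting 0 were called, but none could be, since leaving out the 3 libraries with the highest 18S level gave 0 calls in every comparison. Of the 194 not called, 113 were called under at least 1 setting. The 70 called values had 0 changes of sign under any setting, while changes of sign in values called in neither fit were not counted. Of 50 simulated changes in genes with a mean of at least 5 TPM, 1 was found at 2-fold and 39 at 8-fold. The fit gives each gene 1 spread for all 5 groups, so the wide gap of the 48 h replicates enters every comparison. SOX17 had SE 1.36 both at 6 h, where its SD was 0.00238 TPM, and at 48 h, where it was 516 TPM. How far this accounts for the moves listed here was not tested.

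Counts are given as genes called at 6 h, 12 h, 24 h and 48 h, over the 3 steps and over the course, against 11, 10, 30, 55, 5, 13, 12 and 66. Leaving out 1 library gave 4 to 36, 4 to 44, 7 to 156, 7 to 437, 2 to 22, 7 to 70, 11 to 92 and 28 to 408, a persistence of 0 to 47.22%, a relation of the first and last step of -0.1711 to 0.0054 and 38 to 47 list calls. Without a library its group has 1 sample, which is assumed to vary like the others. Without a filter the last 2 steps gave 23 and 32. A filter of 5 TPM gave 5 at 6 h and 1, 7 and 7 over the steps. A pseudocount of 0.1 gave 7 at 6 h, 19 at 24 h, and 3 and 6 over the first 2 steps. TMM gave 18 at 24 h and 24 over the course, upper quartiles 16 and 26. Without the trend the first step gave 2. With a 2-fold minimum no count changed.

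Spans over 200 bases gave 38, 83, 280, 551, 20, 95, 124 and 716, with a relation of -0.1946. With TMM they gave 1, 3, 11, 270, 0, 2, 0 and 9, a persistence of 100% (1 gene) and a relation of -0.2044. The 0 counts had 278 and 1656 at an unadjusted p under 0.05. Prior degrees of freedom were 5.80 in the main fit, 112.8 over 200 bases and 2.43 when these were rescaled by TMM. These counts therefore do not compare spans or scaling alone. At 48 h calls over 200 bases fell from 551 to 270 with TMM, while the unadjusted count rose from 1662 to 3126. SOX17 at 48 h had SE 1.36 in the main fit and 0.59 over 200 bases. Without nested genes spans over 200 bases gave 59, 100, 328, 588, 26, 124, 148 and 791, with -0.1797. Voom gave 0, 0, 80, 354, 0, 0, 0 and 14 (603, 751, 239, 1060 and 1754 unadjusted where 0), and over 200 bases 0, 0, 81, 367, 0, 0 and 0 (572, 706, 202, 1009 and 1681 unadjusted where 0), with -0.1897. With no gene called at 6 h it gives no persistence. Without the 3 libraries with the highest 18S level (ESC replicate 2, 6 h replicate 2 and 24 h replicate 1) all 8 counts were 0 by limma (300, 331, 558, 1209, 204, 324 and 487 unadjusted, in the order of the first 7). With 1 library left in each of these groups the lost calls say little about 18S, and the streak list stayed 2.60, 2.93, 3.99 and 2.83 above all genes. With 18S as a covariate they were 6, 5, 11 and 18 at the times, 3 and 6 over the first 2 steps and 21 over the course, with a relation of -0.1779. The compared groups alone gave 94, 299, 472, 557, 107, 50 and 40. The share of higher calls, 63.64%, 50%, 83.33% and 81.82% at the times, was 50%, 33.33%, 61.11% and 70.77% with TMM.

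With a replicate block 54 genes were called at 24 h, and with TMM and the block 6 at 12 h, 14 at 24 h, 36 at 48 h, 6 over the second step and 17 over the course. The deviations from the group means that go with the replicate number had a correlation of 0.344 between ESC and 6 h (0.292 after TMM), and of -0.124 to 0.134 between other groups.

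Of 2369 list results under alternatives 88 lost and 83 gained a call, and in 21 the test's direction was reversed. These 21 are given as medians relative to all genes, which kept their sign in some. Histones at 6 h ranged from -0.59 (without ESC replicate 1; -0.52 without 6 h replicate 2) to 1.04 without 1 library and were at -0.33 with the 18S covariate. At 12 h they ranged from -1.34 to 0.10 (without ESC replicate 2) and were at 0.21 without the 3 libraries with the highest 18S level. At 24 h they ranged from -0.55 to 0.76 (without ESC replicate 2; 0.42 without 24 h replicate 2) and were at 0.53 without those 3, and at 48 h from -1.35 to 0.0268 (without ESC replicate 2) and at -0.0012 without those 3. ATF4 targets at 6 h ranged from -0.49 to -0.0444 (without 6 h replicate 1; -0.07 without ESC replicate 2), and at 24 h from -0.71 to 0.27 (without 24 h replicate 1) with 0.54 without those 3. Ribosomal proteins at 12 h ranged from -0.0258 (without ESC replicate 2; -0.0246 without 12 h replicate 1) to 0.35, with -0.0229 without those 3, and at 24 h were at -0.0905 without those 3. Neuroectoderm at 6 h ranged from -1.51 to -0.63 (without 6 h replicate 1), cholesterol synthesis at 12 h from -0.78 to 0.0811 (without 12 h replicate 1) and mesoderm at 24 h from -0.10 (without 24 h replicate 2) to 1.02. Streak and Activin/Nodal lists at all times, and endoderm (24 h and 48 h) and cholesterol synthesis (6 h, 24 h and 48 h) lists, were called under all 27 settings, and none of them with an estimated correlation (adjusted p = 0.32 or more).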

Other observations

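Of the tests here, those on the 48 h libraries, on the 18S level and on the ribosomal RNA records were chosen after the result was seen, and those on reads over genes and on short spans before. At 24 h MT1H, a metallothionein, rose from 0.597 TPM in ESC to 78.5 ± 17.7 TPM (5.73, adjusted p = 0.01), MT2A from 16.9 ± 4.79 TPM to 398 ± 142 TPM (adjusted p = 0.019) and SLC30A2, a zinc transporter of vesicles, to 3.76 ± 0.692 TPM (adjusted p = 0.0234). MT1E and MT1G, at 211 TPM and 310 TPM, were not called (adjusted p = 0.0714 and 0.187), and nor was the zinc exporter SLC30A1 (0.116). At 48 h MT2A had 183 and 37.8 TPM. These genes were chosen after their values were seen, and the metallothioneins can share reads. The MT1H call was lost without ESC replicate 1 and those of MT2A and SLC30A2 without either ESC or 6 h library or 24 h replicate 1.

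Other genes called at 48 h, also chosen after their values were seen, were SERPINE2, a protease inhibitor that rose from 6.6 ± 1.35 TPM to 62.5 ± 28 TPM (adjusted p = 0.0257), COL5A2, a collagen chain (4.69 ± 0.314 TPM to 27.3 ± 13.4 TPM, adjusted p = 0.0465), CYP1B1, a cytochrome P450 (1.39 TPM to 20.8 TPM, adjusted p = 0.0061), CXCL14, a chemokine (2.38 TPM to 20.6 TPM, adjusted p = 0.041), and PPP1R15A, a phosphatase subunit of the stress response (22.8 TPM to 135 TPM, adjusted p = 0.0465). CST2 and CST4, relatives of CST1, rose as well (adjusted p = 0.0287 and 0.00786). CYP1B1 was called without each library in turn, and the other 6 were lost without either ESC library. The calls of COL5A2, CXCL14, PPP1R15A and CST2 were also lost without either 6 h library, the first 3 of these without 48 h replicate 1, COL5A2 without any 1 of the 12 h and 24 h libraries and PPP1R15A without 12 h replicate 2.

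Endoderm markers were far lower in 48 h replicate 2 than in replicate 1. Scaling does not account for it, since after rescaling the median gap of the 13 raised members was 4.01 log2 (quartiles 3.05 to 4.44). Cells with ESC levels mixed into replicate 2 would hold every change back alike, but among members changed at least 2-fold in replicate 1 the median part of the change seen in replicate 2 was 0.767 for cholesterol synthesis (quartiles 0.643 to 0.839, 18 genes), 0.0359 for endoderm (0.0319 to 0.0676), 0.0912 for streak and 0.34 to 0.689 for 5 other lists. A library of ESC, 6 h or 12 h under this label is argued against by 17 genes in which both 48 h libraries lay at least 2-fold beyond the other 8. At most 2 did so for 48 h replicate 1 with any ESC, 6 h or 12 h library (44 with 24 h replicate 1). GPR37, BNIP3 and SLC2A3 were among the 17. Not all are independent, since SLC2A14 can share reads with SLC2A3, and SNORD3B-1 and SNORD3B-2 had equal values. Of the 17, 11 were higher and 6 lower in the 48 h libraries. Among the 6 lower, RPPH1, HIST1H3B, SNORD3B-1 and SNORD3B-2 were highest in the 3 libraries with the highest 18S level, and CXCL12 and PCAT14 were not. Those that go with 18S may reflect the make-up of the libraries and weigh less here. Against a 24 h library stands a place at -0.0861 (quartiles -0.133 to -0.0336) on a scale from the other libraries (0) to 24 h (1). It rests on few independent markers, 6 genes specific to 24 h: APLNR, RPL13P5, SLC30A2 and the metallothioneins MT1A, MT1B and MT1H. Slower progress toward endoderm, or cells that met the medium without turning to endoderm, stay open as hypotheses that were not tested, and staining of SOX17 in single cells of further cultures between 24 h and 48 h would tell them apart.

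The lower median TPM of some libraries was weighed against the ribosomal RNA they held. Its relation to 18S (r = -0.878 over 10 libraries) is consistent with ribosomal RNA taking TPM from other genes. With the 228 ribosomal RNA records taken out and each library scaled back, the log2 range of the median was 0.4856 of that deposited (0.55 against 1.13; 0.28 against 0.693 without 6 h replicate 2), so what made up the remaining range stays open. The alternative of fewer reads had the opposite order to the one it needs, with r = -0.479 between reads and median TPM (permutation p = 0.134; Spearman's rho = -0.358, permutation p = 0.311; r = -0.321 without 6 h replicate 1 and 48 h replicate 1). How much ribosomal RNA each sample held before poly(A) selection was not measured.

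The calls at 6 h were all of short records. By an exact binomial test on the recovered reads, which takes no account of spread between replicates and called 3546 genes, 0 of the 11 differed. With at most 4 summed reads each, 0 of the 11 had enough reads for any split to pass. Steps of few reads on short spans, reads of the genes around most of them and a change in these small RNAs therefore cannot be told apart.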
